A study of Scophthalmus maximus with 9 samples.

How the data were processed

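RNA was measured in head kidney neutrophils of turbot (Scophthalmus maximus), a farmed flatfish whose head kidney is the main blood-forming organ. The labels place the 9 libraries in 3 groups of 3. Fish were injected into the body cavity with 100 µL of β-glucan at 1 mg/mL or with the same volume of PBS, and neutrophils were isolated 7 days later, per the series' design text. β-glucan is a cell wall polysaccharide widely used to induce trained immunity, a lasting change in the response of innate immune cells. The isolated cells were exposed to Edwardsiella piscicida, a bacterial pathogen of fish, at a multiplicity of infection of 10 for 2 h. The groups are named PBS (PBS injection, no bacterium named in the labels), PBS_EIB202 (PBS injection, then bacteria) and Glucan_EIB202 (β-glucan injection, then bacteria), EIB202 being the bacterial strain. No group of β-glucan-injected fish without bacteria was analysed here. The labels do not say whether the 3 libraries of a group came from separate fish or separate cultures, so p-values measure only the spread between these libraries, which may be technical.

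Per the labels' protocols, RNA was extracted with Trizol, poly-A RNA was selected with poly-T beads, libraries were made with a NEBNext Ultra RNA kit, and paired-end reads of 150 bases were sequenced on an Illumina NovaSeq 6000. Per the submitters' processing notes, Trimmomatic, STAR and HTSeq were used, with no versions given in the sources used here. The authors deposited raw counts per gene, whole numbers that were not normalized. Per the labels' protocols, alignment was to a human assembly (hg38, GENCODE 43), whereas the table's row identifiers are Ensembl turbot gene identifiers. The genome behind the counts is therefore unclear from the sources, and no coordinates are given. Whether HTSeq counted by strand is not given in the sources used here.

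The table has 21020 genes, of which 20987 carry an Ensembl identifier only and 33 carry a symbol. A RefSeq gene table for turbot (assembly ASM2237912v1) holds no Ensembl identifiers, so none of the identifiers could be turned into a name. All named results therefore concern the 33 genes with a symbol, a set fixed by the table and not by the values, plus, per comparison, the 2 identifiers that rose most and the 2 that fell most among called genes with a mean log2 CPM of at least 2 and groups that do not overlap. Less abundant genes had larger falls. These 33 genes hold 1.17 to 1.49% of a library's counts. No count column was left unused.

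Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 13570 genes, 30 of them with a symbol. Libraries were scaled by the trimmed mean of M values (TMM). A robust quasi-likelihood model with 1 mean per group was fitted to all 9 libraries, so that the groups share 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all 13570 genes for a comparison, two-sided, and a gene is said to have risen or fallen where this value is under 0.05. Standard errors were obtained from the log2 fold change and the F statistic. Levels are CPM, the library's counts scaled to a common total with the TMM factors, given as mean ± SD over 3 libraries. Shares of counts in percent are of a library's unscaled total, without the TMM factors.

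The comparisons, tests, the rule for named genes, the gene lists and most alternatives were set before the data were examined. The rule took the 8 largest rises and 8 largest falls with a name, adjusted p under 0.05, mean log2 CPM of at least 2 and groups that do not overlap, a fixed panel of inflammatory and neutrophil genes, and up to 4 members of each described list. No panel gene had a named entry. Of 34 gene lists, 3 had named members by the rule for matching symbols: mitochondrially encoded genes (13 tested), T and NK cell markers (4 tested) and leukocyte recruitment receptors (1 tested). The matching rule did not accept the suffixes of ighm_m and ighm_s, so they did not count as ighm of the B cell list. In the same way ifng1 did not count as ifng of the inflammatory cytokines. The mitochondrial genes matched after their MT_ prefix was removed, a change made after the symbols were seen. Only the mitochondrial list reached the minimum of 5 members, so it was the only list tested, with limma 3.58.1 (camera at a preset correlation of 0.01 and at an estimated correlation, and fry). No list of neutrophil genes had a named member, so the purity of the cells was not checked with neutrophil genes. Immunoglobulin and T cell receptor transcripts were present, with ighd at 1085 to 1570 CPM and trbc2 at 90.9 to 159.8 CPM as group means. Whether the mix of cells differed between groups was not tested, for these or any other genes.

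The alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, no filter, a filter of CPM 1 in 3 libraries, a fit of the 6 libraries compared, the replicate number as a block, a 2-fold threshold and each library left out in turn. Scaling by total counts was added after the TMM factors were seen to differ between groups. The PBS_EIB202 libraries enter both main comparisons with opposite sign, so 100 sets of 9 unchanged libraries were simulated to give the relation between the comparisons that this alone produces.

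Totals ran from 10960607 to 11628647 counts per library, and 3 counts, the floor used for detection, correspond to 0.247 to 0.259 CPM in the PBS and PBS_EIB202 libraries and 0.297 to 0.303 CPM in Glucan_EIB202. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Every pair of replicates differed by more than sampling noise: the chi-square per degree of freedom was 5.96 and 5.39 for PBS replicate 1 against the other PBS replicates and 2.00 to 3.15 for all other pairs, and no columns were identical. The common biological coefficient of variation was 5.38%. The procedure was tested on simulated data with 50 genes changed at each of 4 fold sizes. All other genes were unchanged, and rises and falls were equal in number. The test therefore does not show how TMM scaling behaves where 40.7% (training) or 49.8% (infection) of genes are called. For infection, run on 13338 genes, 23 of 50 changes of 1.25-fold, 34 of 49 of 1.5-fold, 46 of 50 of 2-fold and 49 of 49 of 4-fold were recovered, with 10 false calls. For training, run on 13260 genes, the numbers were 20 of 49, 36 of 50, 47 of 49 and 47 of 48, with 8 false calls. Figures were drawn with matplotlib 3.10.9.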

Results

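Poly-A RNA was sequenced from 9 libraries of turbot head kidney neutrophils, 3 for each of 3 groups: cells from PBS-injected fish (PBS), cells from PBS-injected fish exposed to E. piscicida for 2 h (PBS_EIB202), and cells from β-glucan-injected fish exposed in the same way (Glucan_EIB202). Total counts were 11195707, 10960607 and 11146287 in the PBS libraries, 11628647, 11079016 and 11178510 in PBS_EIB202, and 11320961, 11085782 and 11408169 in Glucan_EIB202. On average 17330, 17020 and 16900 genes had a count in the respective groups. The first principal component of log2 CPM held 53.6% of the variance and set the PBS libraries apart from both exposed groups, and the second held 21.1% and separated PBS_EIB202 from Glucan_EIB202. The TMM scaling factors were 1.06 to 1.09 in PBS, 1.04 to 1.06 in PBS_EIB202 and 0.871 to 0.894 in Glucan_EIB202. The 100 most abundant genes of a library held 31.6% ± 0.432 of its counts in PBS, 29.95% ± 0.214 in PBS_EIB202 and 34.1% ± 0.559 in Glucan_EIB202.

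The first comparison asks how neutrophil preparations from PBS-injected fish responded to the bacteria (PBS_EIB202 against PBS). Transcripts of the mitochondrial genome were mostly lower after exposure, and those of the T cell receptor beta chain were higher. MT_COX1, the catalytic core of cytochrome c oxidase, fell from 4655 ± 232 to 3574 ± 120 CPM, and MT_ND1, a subunit of respiratory complex I, fell from 309.7 ± 12.7 to 198.7 ± 5.3 CPM (SD, n = 3). trbc2, a constant region of the T cell receptor beta chain, rose from 90.9 ± 13 to 159.8 ± 10.1 CPM. cd44b, named for the hyaluronan receptor CD44 that leukocytes use for adhesion, fell from 349.8 ± 11 to 279.8 ± 8.4 CPM, and entpd1, the ectonucleotidase CD39 that degrades extracellular ATP, fell from 101.7 ± 2.42 to 77.0 ± 6.93 CPM.

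Of 13570 genes tested, 6751 changed after infection, 3435 higher and 3316 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 897 changed by 2-fold or more (407 higher and 490 lower) and 99 by 4-fold or more, 87 higher and 12 lower. The median absolute log2 fold change of the called genes was 0.48. The groups did not overlap in 55.7% of tested genes, where chance gives 10% for 3 libraries against 3. Among the 30 tested genes with a symbol, 6 rose, 10 fell and 14 did not pass the test.

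Of the 13 mitochondrially encoded genes, 8 fell, 1 rose and 4 did not pass, and the counts were identical when adjusted over the list alone. MT_ND1 fell by 0.64 on the log2 scale (SE 0.0561, adjusted p 8.94e-12), MT_ND3 by a log2 change of -0.47, MT_ATP6 of -0.43, MT_COX3 of -0.41, MT_COX1 of -0.38 (SE 0.0566, adjusted p 7.77e-07), MT_COX2 of -0.36 and MT_CYTB, the core of complex III, of -0.22 (SE 0.0558, adjusted p 0.00141). MT_ATP8 also fell, from 1.26 ± 0.376 to 0.451 ± 0.178 CPM, at a depth close to the detection floor. MT_ND5 rose slightly, with a log2 change of 0.20 and an adjusted p of 0.0119. MT_ND2, MT_ND4, MT_ND4L and MT_ND6 lay at log2 changes of 0.20, -0.11, -0.25 and 0.12 and did not pass. The list as a whole moved down against other genes (camera p 0.00822), and its median log2 change was -0.36. With an estimated correlation between its genes of 0.419 the p was 0.298. limma's fry test, which asks whether the genes move on balance in a direction, gave a p of 0.00213, and its mixed form, which takes changes in either direction, 1.54e-05. Mitochondrial transcripts made up 1.15% ± 0.0491 of counts in PBS and 0.891% ± 0.0218 in PBS_EIB202.

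**Figure D1:**
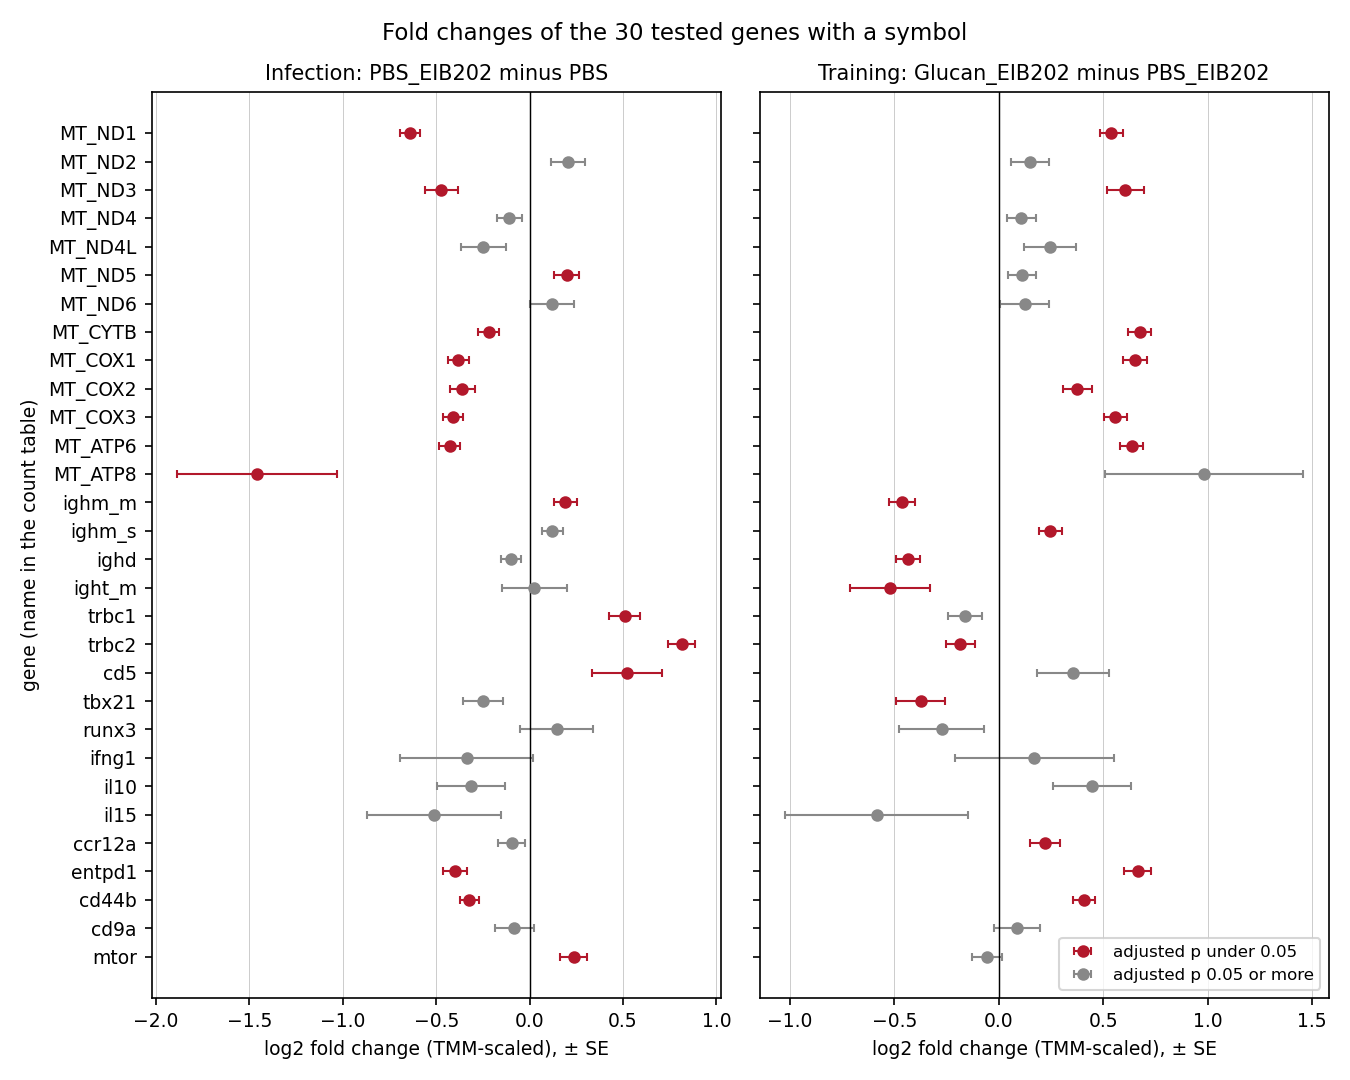
Log2 fold changes on the TMM scale with standard errors for the 30 tested genes with a symbol, after infection (left) and between β-glucan-injected and PBS-injected fish after infection (right); red points have an adjusted p under 0.05. Of the 13 mitochondrial genes, 8 lie below 0 in red on the left and 7 above 0 in red on the right, 6 of which keep that call at equal library totals, where the uncalled MT_ND2, MT_ND4, MT_ND4L, MT_ND5 and MT_ND6 and the called ccr12a turn below 0.

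Both tested T cell receptor genes rose. The log2 change was 0.81 for trbc2 (SE 0.0713, adjusted p 8.17e-11) and 0.51 for trbc1 (SE 0.0828, adjusted p 3.78e-06). Of the T and NK cell markers, 2 of 4 tested members rose over all genes tested, and adjusted over the list alone 2 rose and 1 fell. The risers were trbc1 and cd5, a surface protein of T cells, which went from 3.27 ± 0.404 to 4.70 ± 0.201 CPM with an adjusted p of 0.0192. tbx21, the transcription factor T-bet, had a log2 change of -0.25 and an adjusted p of 0.0535 over all genes, and runx3 one of 0.14 (adjusted p 0.563). T cell receptor genes held 0.0138% ± 0.00198 of counts in PBS and 0.0223% ± 0.00123 in PBS_EIB202. cd8a, a surface protein of cytotoxic T cells, had 0 counts in all 9 libraries, which allows up to 0.247 to 0.259 CPM in the PBS and PBS_EIB202 libraries and 0.297 to 0.303 CPM in Glucan_EIB202.

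Of 4 tested immunoglobulin heavy chain genes, 1 rose: ighm_m, from 142.0 ± 9.34 to 162.0 ± 11.2 CPM (adjusted p 0.0106). The labels do not explain the suffixes of ighm_m and ighm_s, and the counting could split reads between such entries. ighm_s had a log2 change of 0.12 (adjusted p 0.0727), ighd, the IgD heavy chain, of -0.10 (adjusted p 0.139) and ight_m of 0.03 (adjusted p 0.914). None of the 3 tested cytokine genes passed: the log2 changes were -0.34 for ifng1, -0.31 for il10 and -0.51 for il15, with adjusted p of 0.455, 0.158 and 0.241. mtor, the growth-regulating kinase, rose from 77.5 ± 9.58 to 91.2 ± 3.2 CPM (adjusted p 0.00662). The chemokine receptor ccr12a, the single tested member of the leukocyte recruitment receptors, had a log2 change of -0.10 (adjusted p 0.268), which also failed when adjusted over the list alone. cd9a lay at -0.08 (adjusted p 0.549).

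Among genes without a symbol, ENSSMAG00000005337 rose from 1.31 ± 0.161 to 72.8 ± 6.93 CPM, a log2 change of 5.78 (SE 0.127, adjusted p 2.93e-29). ENSSMAG00000002666 had 1, 1 and 2 counts in the PBS libraries against 113, 113 and 120 in PBS_EIB202, a ratio of 87.1 with a 95% counting interval of 33.7 to 322 (exact binomial). ENSSMAG00000011669 fell from 9.76 ± 2.29 to 2.40 ± 0.71 CPM and ENSSMAG00000016890 from 16.97 ± 2.33 to 4.33 ± 1.1 CPM, with log2 changes of -2.02 and -1.97. The cd5 call was lost with the DESeq2 test and without PBS replicate 2, PBS replicate 3 or PBS_EIB202 replicate 3, the ighm_m call without PBS replicate 3 or PBS_EIB202 replicate 1, the MT_ND5 call without PBS replicate 1 or PBS_EIB202 replicate 3, and the mtor call without PBS replicate 1. Without PBS replicate 1 the fall of MT_ND4 (log2 change -0.20, adjusted p 0.00357), MT_ND4L (-0.35, 0.012) and tbx21 (-0.36, 0.0037) and the rise of ighm_s (0.17, 0.0116) passed, and without PBS replicate 3 the changes of MT_ND2 (0.31, 0.00185), ccr12a (-0.17, 0.0464), ighd (-0.16, 0.022) and il10 (-0.47, 0.0421). Without PBS_EIB202 replicate 2 ighm_s (adjusted p 0.0401) and MT_ND2 (0.0404) passed, and without PBS_EIB202 replicate 3 tbx21 (0.0479). At equal library totals ighd and tbx21 passed, with log2 changes of -0.14 and -0.28 and adjusted p of 0.0338 and 0.0283.

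The second comparison asks how exposed neutrophil preparations differed after prior β-glucan injection (Glucan_EIB202 against PBS_EIB202), the subject of the series. Of 13 mitochondrial transcripts, 7 were higher in cells from β-glucan-injected fish, and 3 of 4 tested immunoglobulin heavy chain transcripts were lower. MT_COX1 rose from 3574 ± 120 to 5622 ± 285 CPM and MT_CYTB from 2005 ± 45.1 to 3201 ± 68.9 CPM (SD, n = 3). ighd fell from 1465 ± 29.8 to 1085 ± 20.3 CPM and ighm_m from 162.0 ± 11.2 to 117.6 ± 7.45 CPM. entpd1 rose from 77.0 ± 6.93 to 122.1 ± 6.77 CPM and cd44b from 279.8 ± 8.4 to 371.8 ± 2.34 CPM.

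Of 13570 genes tested, 5524 differed, 3069 higher and 2455 lower in Glucan_EIB202 (edgeR, adjusted p under 0.05). Of these, 320 differed by 2-fold or more, 208 higher and 112 lower, and 18 by 4-fold or more, 10 higher and 8 lower. The median absolute log2 fold change of the called genes was 0.44, and the groups did not overlap in 50.4% of tested genes, where chance gives 10%. The balance of rises and falls depended on scaling: at equal library totals 1387 genes were higher and 5554 lower, 3842 of the 6941 being called on the TMM scale too. The median log2 change of all tested genes was 0.02 on the TMM scale and -0.23 at equal totals, and the changes given are relative to the TMM scale. Of the 30 tested genes with a symbol, 11 rose, 5 fell and 14 did not pass.

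Of the 13 mitochondrially encoded genes, 7 rose, none fell and 6 did not pass, with 7 rising also when adjusted over the list alone. The largest rise was that of MT_CYTB, with a log2 change of 0.67 (SE 0.056, adjusted p 4.96e-12). It was followed by MT_COX1 (0.65, SE 0.0568, adjusted p 1.43e-11), MT_ATP6 (0.64), MT_ND3 (0.60), MT_COX3 (0.56), MT_ND1 (0.54, SE 0.0564, adjusted p 8.96e-10) and MT_COX2 (0.38, adjusted p 5.71e-05). MT_ATP8 had a log2 change of 0.98 with an SE of 0.473 and did not pass (adjusted p 0.0967). MT_ND2, MT_ND4, MT_ND4L, MT_ND5 and MT_ND6 lay between 0.11 and 0.24, and all 5 turned below 0 at equal library totals. The list moved up against other genes (camera p 6.05e-05), with a median log2 change of 0.54. With an estimated correlation the p was 0.134. limma's fry test gave a p of 0.00019, and its mixed form 8.62e-06. At equal library totals 6 of the 13 rose and MT_COX2 no longer passed, with a log2 change of 0.13 and an adjusted p of 0.0835. Mitochondrial transcripts made up 1.13% ± 0.0329 of unscaled counts in Glucan_EIB202 against 0.891% ± 0.0218 in PBS_EIB202.

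All 4 tested immunoglobulin heavy chain genes changed, 3 lower and 1 higher. The log2 change was -0.43 for ighd (SE 0.056, adjusted p 7.37e-08), -0.46 for ighm_m (SE 0.0634, adjusted p 2.41e-07) and -0.52 for ight_m, named for the teleost IgT heavy chain (SE 0.192, adjusted p 0.0282). ighm_s rose from 408.7 ± 18.8 to 485.0 ± 18.9 CPM on the TMM scale, with a log2 change of 0.25 (adjusted p 0.000477), whereas at equal totals its log2 change was 0.00395 with an adjusted p of 0.956. Immunoglobulin genes held 0.214% ± 0.00537 of unscaled counts in PBS_EIB202 and 0.15% ± 0.00358 in Glucan_EIB202. This compares at equal library totals, where the median gene was lower in Glucan_EIB202 too.

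**Figure D2:**
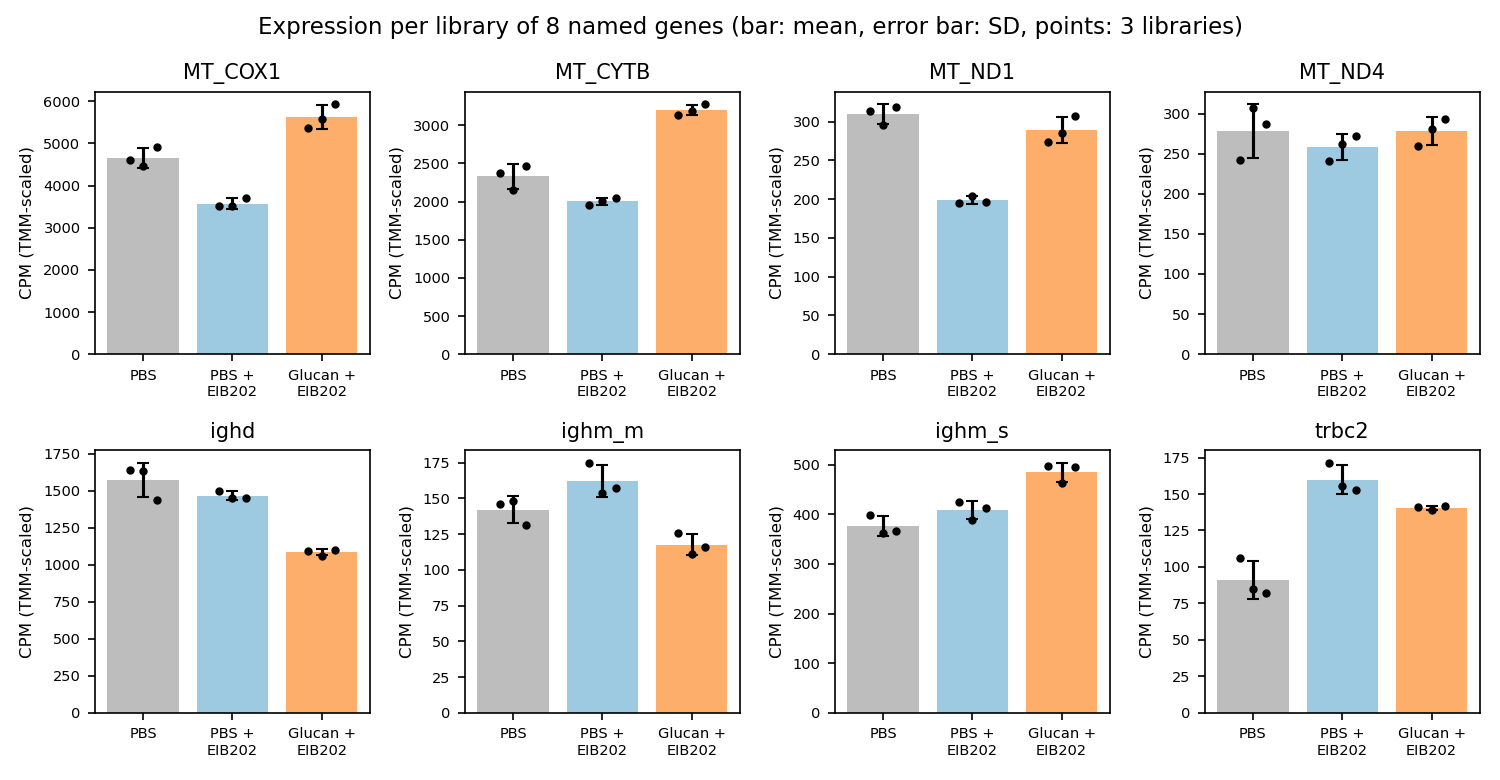
CPM on the TMM scale of 8 named genes in the 3 groups; bars are means, error bars SD and points the 3 libraries. MT_COX1, MT_CYTB and MT_ND1 are lower in PBS_EIB202 than in both other groups, ighd and ighm_m are lowest in Glucan_EIB202, and ighm_s reaches 485.0 CPM there, against a log2 change of 0.00395 from PBS_EIB202 at equal library totals.

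entpd1 rose by a log2 change of 0.66 (SE 0.065, adjusted p 2.10e-10) and cd44b by 0.41 (SE 0.0529, adjusted p 7.36e-08). Of the 4 tested T and NK cell markers, 1 fell, over all genes and adjusted over the list alone: tbx21, from 18.8 ± 1.88 to 14.5 ± 0.633 CPM (adjusted p 0.00986). The log2 changes of the others were 0.35 for cd5 (adjusted p 0.102), -0.16 for trbc1 (adjusted p 0.114) and -0.27 for runx3 (adjusted p 0.301). trbc2 fell from 159.8 ± 10.1 to 140.6 ± 1.33 CPM (adjusted p 0.0349). T cell receptor genes held 0.0167% ± 0.00021 of unscaled counts in Glucan_EIB202 against 0.0223% ± 0.00123 in PBS_EIB202. Such shares compare at equal library totals, where the median gene was lower in Glucan_EIB202 too. ccr12a, the tested member of the leukocyte recruitment receptors, rose by a log2 change of 0.22 (adjusted p 0.0125), a call that also held when adjusted over the list alone. The 3 tested cytokine genes did not pass: il10 lay at 0.45 (adjusted p 0.0545), il15 at -0.58 (adjusted p 0.3) and ifng1 at 0.17 (adjusted p 0.756). mtor had a log2 change of -0.06 (adjusted p 0.571) and cd9a of 0.09 (adjusted p 0.554).

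Among genes without a symbol, ENSSMAG00000004923 rose from 1.63 ± 0.307 to 23.2 ± 2.59 CPM, a log2 change of 3.82 (SE 0.194, adjusted p 1.25e-16). ENSSMAG00000021004 rose from 9.72 ± 0.452 to 45.7 ± 0.947 CPM. ENSSMAG00000001471 fell from 7.28 ± 1.4 to 1.66 ± 0.743 CPM and ENSSMAG00000002503 from 14.8 ± 0.322 to 4.40 ± 0.649 CPM, with log2 changes of -2.12 and -1.75. The trbc2 call was lost with DESeq2 and without PBS_EIB202 replicate 1 or any Glucan_EIB202 replicate, the ight_m call with DESeq2 and without PBS_EIB202 replicate 2 or 3 or Glucan_EIB202 replicate 1 or 2, the tbx21 call without PBS_EIB202 replicate 3, and the ccr12a call without PBS_EIB202 replicate 2 or Glucan_EIB202 replicate 3. MT_ND4L passed without Glucan_EIB202 replicate 1 (log2 change 0.39, adjusted p 0.0139) and trbc1 without Glucan_EIB202 replicate 3 (-0.23, 0.0435). At equal totals ccr12a turned to -0.02 and was not called, while trbc1, mtor and runx3 passed as lower, with log2 changes of -0.41, -0.30 and -0.52 and adjusted p of 0.000135, 0.00126 and 0.0359.

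Genes strongly induced by infection in cells from PBS-injected fish were mostly higher still in cells from β-glucan-injected fish. Of the 87 genes that rose 4-fold or more after infection, 63 were higher in Glucan_EIB202 than in PBS_EIB202, 1 was lower and 23 did not differ by the test. With no PBS_EIB202 library in both fold changes, 90.8 to 95.9% of the 74 to 79 genes then found 4-fold or more higher after infection had a training change above 0. The median rise of the 87 genes over PBS, with the PBS_EIB202 libraries shared, was 2.58 ± 0.0411 log2 units in PBS_EIB202 and 3.26 ± 0.037 in Glucan_EIB202 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 allow). At equal library totals 54 of the 87 were higher and 8 lower. This class was chosen after the data were seen, and it was selected on the PBS_EIB202 libraries that also enter the training comparison.

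**Figure D3:**
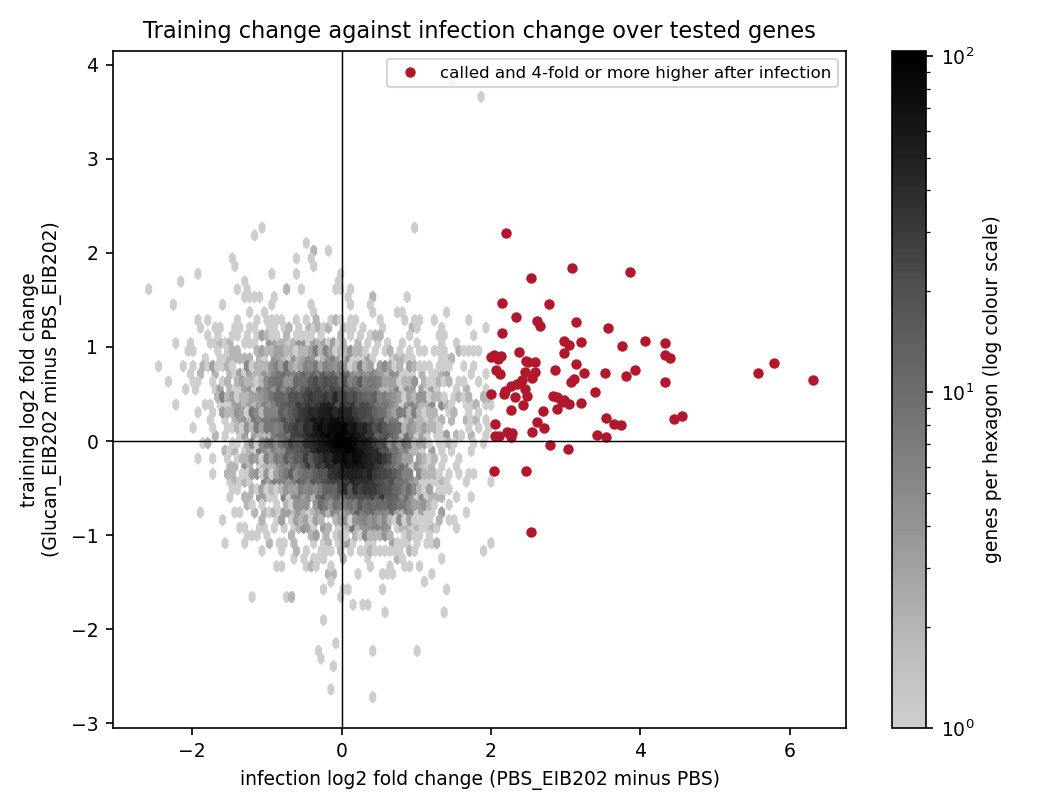
Log2 fold change between Glucan_EIB202 and PBS_EIB202 (vertical) against the log2 fold change after infection (horizontal) for the tested genes, on the TMM scale; grey hexagons count genes on a log colour scale and red points are genes 4-fold or more higher after infection. Of the 87 red genes, 82 lie above 0 on the vertical axis, with a median of 0.65 on the TMM scale and 0.41 at equal library totals.

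Of 320 genes that rose 2- to 4-fold after infection, 119 were higher and 75 lower in Glucan_EIB202 on the TMM scale, against 82 higher and 112 lower at equal library totals. Of 3028 genes that rose by under 2-fold, 1218 were lower and 542 higher, and 2056 and 249 at equal totals. Of 478 genes that fell 2- to 4-fold, 119 were higher and 7 lower on the TMM scale, and 77 and 31 at equal totals. On the TMM scale independent lists would give 108 higher and 86.5 lower. Of 12 genes that fell 4-fold or more, 4 were higher and 0 lower on the TMM scale, and 1 and 0 at equal totals. All 12 had a training change above 0 on the TMM scale, with a median of 0.87, and 0.63 at equal totals. These classes too were selected on the PBS_EIB202 libraries. Of 2826 that fell by under 2-fold, 1152 were higher and 219 lower on the TMM scale, whereas at equal totals 535 were higher and 764 lower. Among the genes with a symbol that changed by under 2-fold after infection, MT_COX1, MT_COX2, MT_COX3, MT_CYTB, MT_ND1, MT_ND3, MT_ATP6, entpd1 and cd44b fell and were higher in Glucan_EIB202, of which MT_COX2 did not pass at equal totals. ighm_m and trbc2 rose and were lower in Glucan_EIB202, although the infection call of ighm_m and the training call of trbc2 were lost when some libraries were left out. In all, 3519 genes were called in both comparisons: 1294 rose and then were lower, 1275 fell and then were higher, 724 were higher in both and 226 lower in both, where independent lists would give 621, 750, 777 and 600. Independence leaves out the PBS_EIB202 libraries, which both comparisons share with opposite sign, and 100 simulations of 9 unchanged libraries, which leave out real changes, gave 0 genes called in both. Genes of the simulated libraries were called with edgeR's likelihood ratio test at the dispersions used to simulate them, not with the quasi-likelihood test. The covariance of the log2 fold changes over the 13570 genes, which are not independent replicates, was -0.0424, against -0.0159 (range -0.0173 to -0.0148) in the same 100 simulations of unchanged libraries, a difference of -0.0265. Their Pearson correlation was closer to none than in the simulations, at -0.175 against -0.484 (range -0.514 to -0.459). Likewise 38.5% of genes had the same sign in both comparisons, against 33.8% (range 32.8 to 34.8%) in the simulations. Real changes, which the simulations leave out, widen both sets of fold changes and so alter the correlation and the share of same signs. These 2 measures therefore cannot show whether the opposition was weaker or stronger than the shared libraries alone gave. The covariance lay beyond its simulated range, on the side of stronger opposition.

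The remaining pair of groups, Glucan_EIB202 and PBS, differs in both injection and exposure. Here 6672 genes differed, 3464 higher and 3208 lower in Glucan_EIB202 (edgeR, adjusted p under 0.05), 1155 of them by 2-fold or more and 199 by 4-fold or more, of which 167 were higher and 32 lower. At equal library totals 8342 genes differed, 1646 higher and 6696 lower. MT_COX1 stood at 4655 ± 232 CPM in PBS and 5622 ± 285 CPM in Glucan_EIB202, and MT_ND1 at 309.7 ± 12.7 and 288.8 ± 16.9 CPM. The MT_COX1 gap rests on the TMM scale. At similar library totals its unscaled counts overlapped, at 53060 to 58027 in PBS and 54253 to 58865 in Glucan_EIB202. Those of MT_ND1 were 3515 to 3786 and 2765 to 3047. Whether β-glucan injection changed the size of the infection response itself was not tested, since unexposed cells of β-glucan-injected fish were not analysed here.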

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

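Total-count scaling, the MT_ matching and the count of strongly induced genes were chosen only after the data were seen; the other settings were planned. Left-out libraries gave 6058 to 6422 genes for infection, 4773 to 5153 for training, 5849 to 6693 for Glucan_EIB202 against PBS, and 57 to 68 strongly induced genes that were higher in Glucan_EIB202. With a 2-fold threshold the counts were 897, 320 and 1155, since fewer genes reach that size. With an estimated correlation between genes 0 lists passed in either comparison (camera p = 0.298 and 0.134, against 0.00822 and 6.05e-05 at the preset correlation). At the preset correlation, left-out libraries gave the mitochondrial list a camera p from 0.00291 to 0.0281 after infection and from 1.68e-05 to 0.000169 in training. The other planned settings gave 5888 (DESeq2) to 7079 (replicate block) genes for infection and 4785 to 5920 for training.

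At equal library totals, these log2 changes turned sign: in training the called ccr12a to -0.023, and the uncalled ifng1 to -0.0705, MT_ND2 to -0.0939, MT_ND4 to -0.137, MT_ND5 to -0.131, MT_ND6 to -0.118, MT_ND4L to -0.000111 and cd9a to -0.155; after infection the uncalled ight_m to -0.00991. The median of all genes at equal totals was -0.23 in training and -0.04 after infection, so this scaling lowers all training changes alike. Without PBS replicate 3, PBS_EIB202 replicate 2 or PBS_EIB202 replicate 3 the uncalled ight_m after infection was -0.0637, -0.0304 and -0.0283 (range -0.0637 to 0.149 over all left-out libraries), and without PBS_EIB202 replicate 3 or Glucan_EIB202 replicate 2 the uncalled ifng1 in training was -0.032 and -0.0362 (range -0.0362 to 0.517); the cause was not tested. Of 16 named genes called after infection, 12 kept the call in 13 alternatives and 4 lost it in some. Of 16 in training 10 kept it and 6 lost it. These 13 leave out the 2-fold threshold, which few named calls reach. After infection MT_ATP8 reached it (log2 change -1.46), while trbc2, next in size, did not (0.81). The largest called training change with a symbol, that of MT_CYTB (0.67), fell short of it. Leaving out a library also made 8 uncalled named genes pass after infection and 2 in training.

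The replicate numbers were not taken to pair the libraries, because 4 of 9 same-number pairs, not all, had a correlation above 0.1 (range -0.073 to 0.22). As a hint of pairing, 5 of 9 libraries correlated best with their own number in both other groups, where chance gives about 1. With the replicate block 7079, 5878 and 7032 genes were called, the mitochondrial list had a camera p of 0.00589 and 2.75e-05 at the preset correlation (0.298 and 0.134 at an estimated correlation without the block), the covariance was -0.0425, 3882 genes were called in both comparisons and 62 strongly induced genes were higher. The block ended no named call and added 6: after infection ighm_s (adjusted p 0.0219), MT_ND2 (0.000967), MT_ND4L (0.0413) and tbx21 (0.0273), and in training MT_ND2 (0.0223) and il10 (0.0471). The floor of 3 counts, 0.247 to 0.303 CPM, limits MT_ATP8, ifng1 and il15.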

Other observations

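The tests on the immunoglobulin genes, the ratio of mitochondrial genes and the class of genes 4-fold or more higher were chosen only after the results were seen. Those of library splits, of the lower median at equal totals and of the shared PBS_EIB202 libraries were set before their own results were seen. Total-count scaling itself, on which the median test rests, was added after the TMM factors were seen to differ.

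The mitochondrial genes did not move as a unit. The ratio of the counts of the cytochrome and ATPase genes to those of the 7 MT_ND genes within a library was 10.7 ± 0.827 in PBS, 9.48 ± 0.12 in PBS_EIB202 and 12.2 ± 0.251 in Glucan_EIB202 (SD, n = 3). This ratio does not depend on library scaling. The MT_ND genes were themselves mixed: MT_ND1 and MT_ND3 moved with the cytochrome and ATPase genes (log2 changes of -0.64 and -0.47 after infection and 0.54 and 0.60 in training). T cell receptor genes were unequal in level: trbc2 stood at 90.9 to 159.8 CPM as group means, while trac, the alpha chain constant region, had 0 to 6 counts per library and was not tested.

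The Glucan_EIB202 libraries had a lower median gene at equal library totals, by a log2 difference of -0.22 in mean log2 CPM. Without the 100 most abundant genes the difference was -0.141, and without the 1000 most abundant -0.0544. Neither value reached the bounds set for 0 or for a shift that abundant genes could not account for, so a few abundant genes and many moderately abundant genes both stay open as sources. The 1000 most abundant genes held 67.0% of counts in Glucan_EIB202 and 62.2% in PBS_EIB202. Both sources are changes in the composition of the counts, and whether β-glucan injection caused a real change of RNA composition was not tested.

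ighm_m, ighd and ight_m were lower in Glucan_EIB202 and ighm_s was not. Library scaling cannot produce this, since the log2 ratio of ighm_s to ighm_m within a library differed by 0.709 between the groups, beyond the spread between libraries (1.34 ± 0.056 in PBS_EIB202 and 2.05 ± 0.059 in Glucan_EIB202). A uniform loss of B cells of 1 kind is argued against by a difference of 0.681 in the log2 ratio of ighm_s to ighd. Both ratios restate the fold changes that defined the pattern, and neither includes ight_m. The rise of ighm_s itself may come from scaling, as its log2 change at equal totals was 0.003952. The matching rule did not accept ighm_m and ighm_s as ighm, so the list of B cell markers had no member to test. A changed share or mix of B-lineage cells was therefore not tested, and reads split between the immunoglobulin entries stay open too.

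Infection and training fold changes had a negative covariance over genes. Noise of single PBS_EIB202 libraries that enters both fold changes cannot be the whole cause. With no library in both fold changes the mean covariance over 3 divisions of these libraries was -0.0255, from -0.0301 to -0.019. An offset common to the 3 PBS_EIB202 libraries would still enter both with opposite sign, so the shared group itself stays open. The hypothesis that β-glucan priming makes the infection response larger stays open: genes 2-fold or more higher after infection had a median training change of 0.255, averaged over the divisions, but genes 2-fold or more lower also had medians above 0 (0.144 to 0.208), where a larger response would put them below 0. These medians depend on scaling: for all libraries they were 0.26 and 0.32 on the TMM scale and 0.01 and 0.08 at equal totals. Genes 4-fold or more higher had medians of 0.62 to 0.68 in the same divisions.

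The 6 libraries of a comparison can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Every division but the real one mixes both groups, so real differences add to the spread within it. Its gene count and list p-value are therefore not those of unchanged libraries. The real division called 6751 genes for infection, 5524 for training and 6672 for Glucan_EIB202 against PBS, in each case 1 of 10 with as many, and the highest other count was 0 (edgeR; at most 394, 459 and 874 genes at an unadjusted p under 0.05). For the mitochondrial list, 5 of 10 divisions gave a camera p as small as the real 0.00822 after infection (smallest other 0.000158), and 2 of 10 as small as the real 6.05e-05 in training (smallest other 1.62e-05).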
